A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

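Total RNA from 3 strains of Saccharomyces cerevisiae was hybridised to 9 Affymetrix yeast expression arrays, 3 arrays per strain. All cultures were glucose-limited chemostats at a dilution rate of 0.1 per h and had been at steady state for at least 5 residence times, per the labels. Cell material was kept frozen and RNA was isolated with a column kit, per the labels' protocols. Strains and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate chemostat cultures, so p-values measure only the spread between these samples, which may be technical.

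The values used are the log2 expression values that the authors deposited, 1 column per array. They were made with RMA in the affy package, per the submitters' processing notes. The versions of both are not given in the sources used here. RMA corrects background, normalizes probe signals between arrays and summarises the probes of each probe set on the log2 scale. Because every array is drawn to the same distribution, a change of total RNA per cell cannot be seen. Changes at the bright end may be compressed, which was not tested. Deposited values ran from 2.19 to 15.51. The probe signals themselves were not analysed here, so probe masking, scan dates and hybridisation batches could not be examined.

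The array holds 10928 probe sets. In the platform's gene table, 7244 of them carry 1 gene, 1 carries several and 3683 carry none. Those without a gene comprise 213 control probe sets and 3470 others. Entries were matched by gene identifier to the R64 table of S. cerevisiae genes, which updated 12 symbols and was used for names and for which genes neighbour each other. It covered 5498 probe sets of 5449 genes. The remaining 1747 named probe sets belong to genes outside that table and served as a measure of background. The 95th percentile of their means, 5.64 on the log2 scale, was taken as the background limit, and 5332 of the 5449 genes (97.9%) had a mean above it. The median was 10.96 for S. cerevisiae genes and 3.90 for the background set. For 47 genes with more than 1 probe set, the brightest over all arrays was used. Another probe set of the same gene passed the test in the same direction for 7 of the 10 such genes called between D126 and REF and for 7 of the 13 called between D126 and D12, and none passed it in the opposite direction. For 115 genes the probe set can also bind transcripts of similar genes, by its name ending, and their values may mix family members.

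Differences between strains were tested with limma 3.58.1 in R 4.3.3. A linear model with strain as its term was fitted to all 9 arrays, followed by empirical Bayes moderation. The fit had 6 residual degrees of freedom per gene and 3.10 prior degrees of freedom. The median standard error of a difference was 0.048 on the log2 scale. Genes were called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over the 5449 genes, and a moderated F-test asked for any difference among the strains. The number of arrays limits the precision of every value.

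The labels number the arrays of each strain but do not say what a number marks. Same-numbered REF and D126 arrays deviated from their strain means together (correlations of 0.13 to 0.22, against -0.23 to 0.05 for other numbers), so a replicate block was weighed for D126 minus REF. Same-numbered D12 arrays did not (-0.34 to -0.08 with REF and -0.28 to -0.02 with D126). Arrays with different numbers reached 0.30 for REF and D12 and 0.24 for D12 and D126. Correlations of this size thus also occur without a shared number, and whether a block exists stays open.

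Gene lists were tested with limma's camera, a competitive test with a preset correlation of 0.01 between genes. Of 37 lists, 35 had the 4 or more measured members required. The lists for the native yeast plasmid and for Ty reading frames matched 0 measured names and were not tested. Each list was also tested by camera with a correlation estimated from the data and by fry, which asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. Adjusted p-values are over the 35 lists of a comparison.

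Named genes follow a rule. In each comparison these are the 8 called genes with the largest positive and the 8 with the largest negative change among those whose 3 values in one strain all lay above the 3 of the other. For each gene list described, up to 3 called members with the largest absolute change are added, or 2 members given as values where none was called. OLE1, CYB5, CBR1, MGA2, SPT23, INO1 and URA3 are always included. In a comparison with no called gene, the 5 genes with the smallest unadjusted p in each direction are given. The text does not name every gene the rule picks, and genes named outside it are said to be so. The tests of genes and lists, the gene lists, the naming rule and all alternative settings but 1 were fixed before the data were examined. Some tests of explanations were chosen later, as said where they are given.

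The pipeline was tested on simulated data with 200 changed genes among 5449 in each of 20 simulations. For D126 minus REF it recovered 53.4% of log2 changes of 0.2, 94.3% of 0.4, 98.9% of 0.6 and 99.9% of 1, with 4.7% false calls among all calls. For D12 minus REF it recovered 52.9% of changes of 0.2 and 96.3% of 0.4, with 5.5% false calls. These simulations drew genes independently and gave each gene the same spread on every array. The real arrays were unequal, with array weights from 0.19 for D12 replicate 3 to 5.22 for D126 replicate 3. The shares recovered and falsely called may therefore differ in the real data. In simulated lists of 30 genes with a within-list correlation of 0.2, camera with the preset correlation called 23.7% of unshifted lists. Camera with an estimated correlation and fry each called 0.2% of them. A list shift of 0.1 was found in 100.0%, 26.0% and 65.0% of the shifted lists by the 3 methods in that order.

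Alternatives tried were centring each array on its median, quantile normalization of the tested probe sets, a filter at the background limit, all non-control probe sets, the mean of a gene's probe sets, an intensity trend or a robust prior, array weights, only the 6 arrays compared, a plain 2-group test per gene, a 2-fold minimum, the replicate number as a block, ranks in camera, and leaving out each array in turn. Expression of the introduced Mucor genes was not analysed here. A further test of an explanation, chosen after the results were seen, is not reported here.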

Results

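Gene expression was measured in 9 arrays from 3 strains of the yeast Saccharomyces cerevisiae. REF is the reference strain, D12 expresses the D12-desaturase of the fungus Mucor rouxii, and D126 expresses both the D12-desaturase and the D6-desaturase of that fungus. A D12-desaturase converts oleic to linoleic acid, and a D6-desaturase converts linoleic to gamma-linolenic acid. Yeast itself makes monounsaturated fatty acids with the desaturase Ole1. Each strain was grown in glucose-limited chemostats at a dilution rate of 0.1 per h and is represented by 3 arrays. Values are log2 expression values normalized by the authors, given as mean ± SD with n = 3 arrays per strain, and differences are log2 changes with their standard error (SE).

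The 3 D126 arrays lay apart from the other 6 along the leading principal component, which held 54.7% of the variance between arrays. D126 scores ran from 7.07 to 10.18, and REF and D12 scores from -5.86 to -2.40. D12 replicate 3 lay at -8.92 on the next component, which held 18.4%, while the other D12 arrays lay at 2.22 and 2.73. The closest arrays were D126 replicates 2 and 3, whose values differed with an SD of 0.062, and REF replicates 1 and 2, with an SD of 0.080. None of 13 array quality measures passed a test for a difference between strains after adjustment (smallest adjusted p = 0.093). They include the difference between 3′ and 5′ probe sets of control transcripts. The test was an exact permutation test of the spread between strain means over 280 splits, which has no direction. Its smallest unadjusted p was 0.007, for the highest value on an array. With 280 splits and 13 measures only the most extreme splits can pass, so a difference in quality is not excluded.

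**Figure D1:**
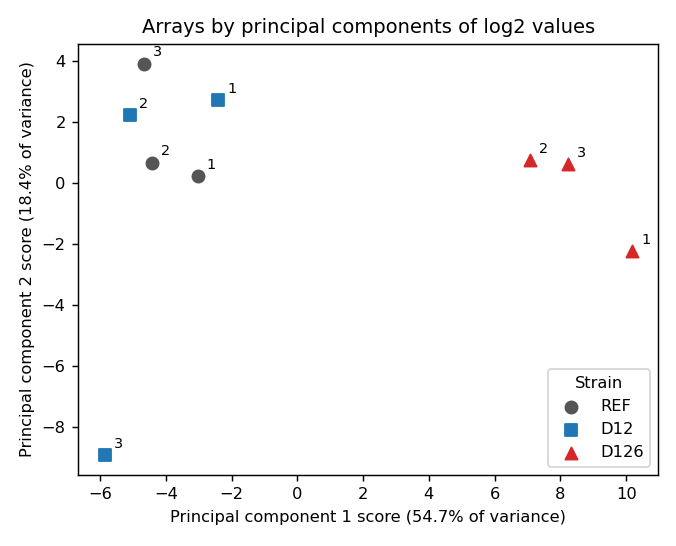
Scores of the 9 arrays on principal component 1 (horizontal axis, 54.7% of variance) and principal component 2 (vertical axis, 18.4%) of the log2 expression values, with 1 point per array and the replicate number beside it. The D126 arrays lie between 7.07 and 10.18 on component 1, and D12 replicate 3 lies at -8.92 on component 2.

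The first comparison asked how expression of the D12-desaturase alone altered the yeast transcriptome. QDR2, a multidrug transporter, stood at 8.31 ± 0.09 in D12, a log2 change of 0.31 (SE 0.05) from REF, and HPF1, a cell wall mannoprotein, at 13.79 ± 0.03 and 13.41 ± 0.08 (log2 change 0.38, SE 0.06). Both had an adjusted p of 0.291, the smallest of any gene. AAD3, a putative aryl-alcohol dehydrogenase read by a shared probe set, stood at 5.92 ± 0.41 in D12 and 6.90 ± 0.10 in REF, an adjusted p of 0.503. The fatty acid desaturase gene OLE1 stood at 14.67 ± 0.02 in D12 and 14.67 ± 0.01 in REF. None of these differences passed the test.

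No gene was called between D12 and REF by limma (0 of 5449), and the plain test per gene also called 0. At an unadjusted p under 0.05 there were 326 genes, 229 higher and 97 lower in D12, where 272 are expected by chance. The median change over all genes was 0.013, and -0.004 with arrays centred on their medians. The excess of higher genes may therefore come from scaling, which was not tested. The 3 values of each strain did not overlap for 554 genes (10.2%), against 10% by chance. Next in order of p were SRD1 (log2 change 0.18), WSC4 (0.20), a sensor of cell wall stress, and SUT1 (0.21), a regulator of sterol uptake, on the higher side. DLD3 (-0.19), a cytosolic lactate dehydrogenase, SCW11 (-0.17), MAL31 (-0.21), a maltose transporter, and CHS2 (-0.19), a chitin synthase, followed on the lower side, each with an adjusted p of 0.503. Among the genes fixed in advance, CYB5 differed by -0.06, CBR1 by 0.01, MGA2 by -0.02, SPT23 by 0.02, INO1 by 0.18 and URA3 by 0.04. AAD3 passed the test with quantile normalization (log2 change -1.01, adjusted p = 0.0463), with array weights (-1.16, adjusted p = 0.00786) and without D12 replicate 3 (-1.22, adjusted p = 0.00337), and its adjusted p over all alternatives ran from 0.00337 to 0.994. Without D12 replicate 2 the maltose permease gene MAL11, named after its values were seen, was the only gene called (-0.38, adjusted p = 0.0157).

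Small shifts of whole gene lists were called between D12 and REF by camera, with 0 called genes in any list. Of the 10 splits of these 6 arrays into 3 and 3, 6, the real one included, called at least the 11 lists of the real split. The highest other count was 14, so the number of list calls does not set D12 apart from REF. Genes of ergosterol biosynthesis, the yeast membrane sterol, were slightly lower in D12: 23 of 25 lay below 0 and the median was -0.04. The adjusted p by camera was 1.99e-06, and the adjusted p = 0.526 with an estimated correlation. ERG26 (-0.12) and ERG24 (-0.10) had the largest differences. Cytosolic ribosomal protein genes were slightly higher, with 108 of 129 above 0 and a median of 0.03 (camera adjusted p = 0.000162). For that list the adjusted p = 0.526 with an estimated correlation. RPL41A (-0.22, on a shared probe set) and RPS14B (0.12) had the largest differences. Adjusted over the list alone, 0 genes of either list were called.

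Camera called 11 of 35 lists in D12, 3 higher and 8 lower. These directions are against the other genes and not against 0, and the median change over all genes was 0.013. A list on the lower side thus need not be lower in D12 than in REF. The others on the higher side were mitochondrial type II fatty acid synthesis (median 0.08, HFA1 0.17 and CEM1 0.14) and the synthesis of leucine, histidine and tryptophan (median 0.05, LEU9 0.18 and HIS5 0.15), with camera adjusted p of 0.029 and 0.0127. Their adjusted p = 0.526 and 0.621 with an estimated correlation, and adjusted over the list alone 1 and 0 of their genes were called. On the lower side were fatty acid synthesis (median -0.01, FAA3 0.10 and ACS2 -0.09), triacylglycerol and steryl ester metabolism (-0.01, YEH1 -0.13 and PAH1 -0.12) and sphingolipid metabolism (-0.02, YSR3 -0.18 and LIP1 0.13), with camera adjusted p of 0.0492, 0.029 and 0.0433. Their adjusted p = 0.526, 0.526 and 0.621 with an estimated correlation, and adjusted over the list alone 0 genes were called in each. Further lower lists were glycolysis (median -0.01, mean 0.00, GPD2 0.36 and ALD5 0.14), copper, zinc and phosphate regulons (-0.04, ZRT1 -0.48 and PHO84 -0.26), cell wall (-0.01, GAS4 0.23 and CHS2 -0.19) and proteasome (-0.03, RPN2 0.08 and UMP1 0.08), with camera adjusted p of 0.0367, 0.00873, 0.0266 and 0.00522. Their adjusted p = 0.526, 0.526, 0.586 and 0.526 with an estimated correlation, and 2 cell wall genes were called adjusted over the list alone. Fry called 0 of the 35 lists (smallest adjusted p = 0.286), and camera with an estimated correlation called 0. Phospholipid synthesis and peroxisomal beta-oxidation were not called (camera adjusted p = 0.228 and 0.367), nor were the markers of MATa cells (0.228), MATalpha cells (0.228) and sporulating cells (0.0575). The peroxisomal list was called without D12 replicate 1 (0.0474), the markers of MATa cells without D12 replicate 3 (0.0358), and those of sporulating cells without D12 replicate 1 (0.00564), D12 replicate 2 (0.0397) or REF replicate 2 (0.0373).

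Most of these calls depended on single arrays. The ranges below are those of the adjusted p over the alternatives run for lists, apart from the estimated correlation given above. Without REF replicate 1 camera called 6 lists in D12. Of the 11 lists, only those of ergosterol and cytosolic ribosomal proteins were called without each of the 9 arrays in turn, with adjusted p of at most 0.00337 and 0.00604. The proteasome call was lost without D12 replicate 1 (0.00106 to 0.0863), and the copper, zinc and phosphate call without REF replicate 1 or D12 replicate 3 (0.000106 to 0.0942). Mitochondrial fatty acid synthesis lost its call without REF replicate 1, REF replicate 2 or D12 replicate 3 (0.0175 to 0.068), and the leucine, histidine and tryptophan list without REF replicate 2, D12 replicate 1 or D12 replicate 2 (4.47e-06 to 0.442). Triacylglycerol and steryl ester metabolism was not called without REF replicates 1 or 2 or D12 replicates 1 or 3 (0.00119 to 0.161), and the cell wall list without REF replicate 3 or D12 replicate 3 (0.0028 to 0.813). Glycolysis was not called without REF replicates 1 or 3, D12 replicates 1 or 3 or D126 replicate 1 (0.00106 to 0.484), and sphingolipid metabolism without REF replicates 1 or 2, D12 replicates 2 or 3 or D126 replicate 1 (0.00106 to 0.813). Fatty acid synthesis was not called without REF replicate 1, D12 replicates 2 or 3 or any D126 replicate (0.0128 to 0.235). Quantile normalization also ended the calls of fatty acid synthesis (0.0812), sphingolipid metabolism (0.0999), glycolysis (0.31) and cell wall (0.117), and centring on medians ended that of sphingolipid metabolism (0.0508).

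The second comparison asked how expression of both desaturases altered the transcriptome. URA3, which encodes orotidine-5′-phosphate decarboxylase of uracil synthesis, fell from 15.32 ± 0.02 in REF to 14.18 ± 0.03 in D126 (adjusted p = 1.29e-07). URA3 thus fell 2.19-fold, or by more if changes near the top of the scale are compressed. Several anaerobic cell wall and seripauperin genes fell with it: PAU24 by 1.48 (SE 0.15), TIR4 by 1.29 (SE 0.16), PAU5 by 1.08 (SE 0.10), PAU3 by 1.05, PAU7 by 1.02 and DAN1 by 0.98 on the log2 scale. Genes that rose include PRY3, a secreted cell wall protein, from 9.73 ± 0.05 to 10.68 ± 0.05, BAR1, the protease that degrades alpha-factor, from 9.96 ± 0.14 to 10.88 ± 0.08, and DSE4, a glucanase of daughter cells, from 9.72 ± 0.06 to 10.59 ± 0.06. Of the listed genes, 24 of 40 of the general stress response and 15 of 25 of ergosterol synthesis fell.

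Limma called 1173 of 5449 genes (21.5%), 468 higher and 705 lower in D126 (592 and 670 with quantile normalization). Most changes were small: the median absolute log2 change of the called genes was 0.23, and 7 genes, all lower, changed at least 2-fold. The 3 values of each strain did not overlap for 2612 genes (47.9%), where chance gives 10%. YDL218W, a gene with no standard name, fell by 1.46 (SE 0.10, adjusted p = 5.88e-05). Other large increases were YNL034W (0.90), which has no standard name, and YBL005W-A (0.91), a Gag reading frame of a Ty element, both on shared probe sets, BUD9 (0.71), a bud-site selection gene, SLS1 (0.78), a mitochondrial inner membrane protein, and GPD2 (0.76), a glycerol-3-phosphate dehydrogenase. PAU24, PAU3 and PAU7 were also read by shared probe sets. Without REF replicate 2 the count was 645, without REF replicate 3 it was 755 and without D126 replicate 3 it was 698, while array weights gave 2615 and a test of all non-control probe sets gave 630. GPD2 lost its call without REF replicate 1 (adjusted p = 0.0623), REF replicate 2 (0.0699) or D126 replicate 1 (0.0548), and its adjusted p over all alternatives ran from 0.000994 to 0.131.

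**Figure D2:**
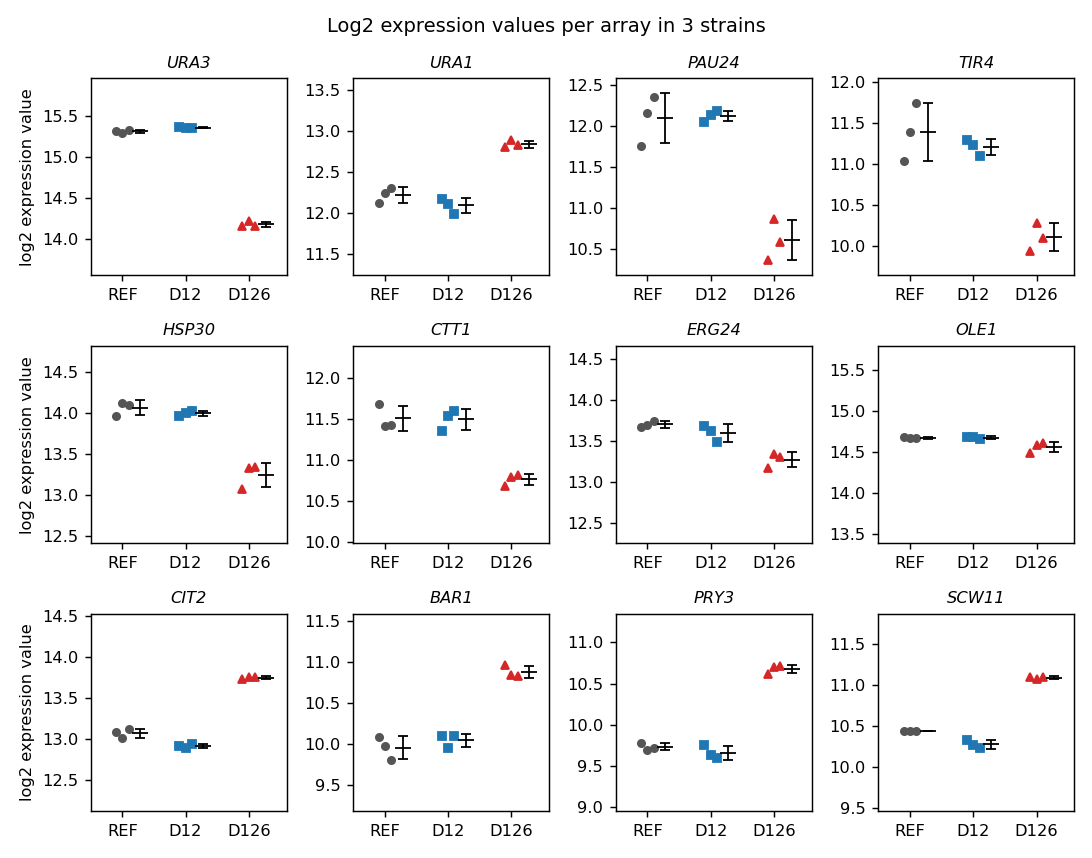
Log2 expression value (vertical axis, scale set per gene) of 12 genes on each of the 9 arrays, by strain, with 1 symbol per array and bars for mean ± SD (n = 3). URA3 stood at 14.18 ± 0.03 in D126 against 15.32 ± 0.02 in REF, BAR1 at 10.88 ± 0.08 against 9.96 ± 0.14, and OLE1 at 14.56 ± 0.06 against 14.67 ± 0.01.

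In lipid metabolism, ergosterol biosynthesis shifted most clearly. In D126, 15 of its 25 genes fell and 0 rose (18 and 0 when adjusted over the list alone), with a median of -0.16. ERG24, a sterol reductase, fell from 13.70 ± 0.04 to 13.27 ± 0.09, IDI1, the isopentenyl diphosphate isomerase, fell by 0.31, and ERG5, a sterol desaturase, fell by 0.24. Camera called the list lower with an adjusted p of 4.34e-07, and the adjusted p = 0.436 with an estimated correlation. Fry gave an adjusted p of 0.00361. The other 6 lipid lists were not called by camera, and fry called 1 of them, triacylglycerol and steryl ester metabolism (adjusted p = 0.0204).

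Of 21 genes of fatty acid synthesis, elongation and desaturation, 1 rose and 4 fell (1 and 8 when adjusted over the list alone; camera adjusted p = 0.324). CYB5, which encodes cytochrome b5, fell from 13.61 ± 0.03 to 13.25 ± 0.11 (adjusted p = 0.00216). The acyl-CoA synthetase gene FAA3 rose from 11.09 ± 0.04 to 11.46 ± 0.01 (adjusted p = 0.00129). MGA2, an activator of OLE1, fell by 0.16 (adjusted p = 0.0187). That call was lost without REF replicate 3 (adjusted p = 0.0719), D126 replicate 1 (0.0546) or D126 replicate 3 (0.0636), within a range of 0.00089 to 0.0805 over all alternatives. OLE1 itself differed by -0.11 (SE 0.04, adjusted p = 0.0602), and its adjusted p over all alternatives ran from 0.0184 to 0.191, with 0.0493 without D12 replicate 3. SPT23, the other activator of OLE1, differed by -0.20 (SE 0.06, adjusted p = 0.0501). Its adjusted p was 0.0472 without D12 replicate 2, 0.00519 without D12 replicate 3, 0.018 with the REF and D126 arrays alone and the replicate block, and between 0.00108 and 0.148 over all alternatives. CBR1, a cytochrome b5 reductase, differed by 0.10 (adjusted p = 0.161).

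Among phospholipid genes, 2 of 27 rose and 1 fell (2 and 1 when adjusted over the list alone), with GEP4 of cardiolipin synthesis up 0.41 and the regulator INO2 down to 9.70 ± 0.06 from 10.04 ± 0.12. INO1, the inositol-3-phosphate synthase gene, differed by 0.03 (adjusted p = 0.736). In triacylglycerol and steryl ester metabolism, 2 of 21 genes rose and 4 fell (2 and 6 when adjusted over the list alone), with AYR1 falling by 0.31 and SLC1 rising by 0.24. Of 26 sphingolipid genes, 0 rose and 5 fell (0 and 5 when adjusted over the list alone), among them the ceramidase gene YPC1 and the glucan synthesis gene SKN1, which fell by 0.25 and 0.24. The sphingolipid median was 0.02 and the mean -0.01. In peroxisomal beta-oxidation, 2 of 26 genes rose and 4 fell (2 and 5 when adjusted over the list alone), with YAT1 up 0.37, and ECI1 and POT1 falling by 0.40 and 0.36. In mitochondrial fatty acid synthesis, 4 of 11 genes rose and 1 fell (4 and 1 when adjusted over the list alone), with ACP1 up 0.23 and HFA1 up 0.22. Camera's adjusted p for these 5 lists ran from 0.118 to 0.9. Without REF replicate 3 it was 0.0419 for triacylglycerol and steryl ester metabolism, the lowest over all alternatives. The highest for that list was 0.523 with an estimated correlation and 0.228 over the other alternatives.

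Many stress genes fell in D126. Of 40 genes of heat shock and the general stress response, 24 fell and 1 rose (25 and 1 when adjusted over the list alone), with a median of -0.15. HSP30, a plasma membrane heat shock protein, fell from 14.06 ± 0.09 to 13.24 ± 0.15 (adjusted p = 0.000212), RTN2 fell by 0.73 and GRE1 fell by 0.57. The camera adjusted p of the list was 1.47e-07, and the adjusted p = 0.38 with an estimated correlation. Of 37 oxidative stress genes, 14 fell and 3 rose (15 and 3 when adjusted over the list alone), with the cytosolic catalase gene CTT1 falling from 11.50 ± 0.15 to 10.76 ± 0.07, OYE3 by 0.57 and TSA2 by 0.53. The camera adjusted p of these was 0.00447, and the adjusted p = 0.436 with an estimated correlation. Of 15 genes of quiescence and starvation, 8 fell and 0 rose (8 and 0 when adjusted over the list alone), among them HBT1 by 0.63 and FMP45 by 0.56; GRE1 belongs to this list as well. The camera adjusted p was 0.00171, and the adjusted p = 0.298 with an estimated correlation. Fry called all 3 lists, with adjusted p of 0.0014, 0.00297 and 0.000625.

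Of 26 genes of the unfolded protein response, 7 rose and 1 fell (9 and 1 when adjusted over the list alone), with SIL1 and LHS1, nucleotide exchange factors of the ER chaperone Kar2, up 0.36 and 0.23. The list passed camera (adjusted p = 0.0162), and the adjusted p = 0.562 with an estimated correlation. Fry did not call the list (adjusted p = 0.105), and camera's call was lost without REF replicate 3 or D126 replicate 2 (highest adjusted p = 0.0544; lowest over all alternatives 0.00138).

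Among 32 hypoxia and heme-dependent genes, 12 fell and 1 rose (13 and 1 when adjusted over the list alone), with a median of -0.11 and a mean of -0.25. The members that fell most, PAU24, TIR4 and DAN1, encode cell wall mannoproteins of anaerobic growth. The camera adjusted p was 0.000403, and the adjusted p = 0.355 with an estimated correlation; fry gave 0.00155. Of 8 galactose genes, 5 fell and 1 rose (6 and 1 when adjusted over the list alone), with the galactokinase gene GAL1 down from 8.85 ± 0.00 to 8.49 ± 0.06 and GAL7 from 7.71 ± 0.02 to 6.94 ± 0.18. GAL10 was below the background limit in both strains. For galactose genes the camera adjusted p was 0.0223, and the adjusted p = 0.477 with an estimated correlation. Fry gave 0.0154.

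Some mitochondrial genes rose by small amounts, and most members of these lists were not called. Of 41 genes of the respiratory chain and ATP synthase, 12 rose and 1 fell (21 and 1 when adjusted over the list alone), with a median of 0.11 and 39 members above 0. ATP14, an ATP synthase subunit, rose by 0.28, and NDE2, an external NADH dehydrogenase, fell by 0.33. Respiratory genes had a camera adjusted p of 8.89e-08, and the adjusted p = 0.477 with an estimated correlation. Of 66 mitochondrial ribosomal protein genes, 18 rose and 1 fell (31 and 1 when adjusted over the list alone), with a median of 0.16 and 65 above 0. RSM27 rose by 0.35 and MRP10 by 0.33. Their camera adjusted p was 2.26e-11, and the adjusted p = 0.519 with an estimated correlation. Of 30 genes of the TCA and glyoxylate cycles, 7 rose and 1 fell (8 and 1 when adjusted over the list alone). CIT2, the peroxisomal citrate synthase, rose from 13.07 ± 0.05 to 13.74 ± 0.01 (adjusted p = 1.39e-05), CIT3 by 0.51 and ICL2 by 0.38. The cycle genes had a camera adjusted p of 0.000787, and the adjusted p = 0.519 with an estimated correlation. Fry gave adjusted p of 0.0235, 0.051 and 0.0211 for the 3 lists in that order.

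Of 129 cytosolic ribosomal protein genes, 11 rose and 0 fell (7 and 0 when adjusted over the list alone), with a median of 0.06. The called share is close to that of all genes called higher (468 of 5449). RPS22A rose by 0.23, while 123 of the 129 genes lay above 0. The camera adjusted p was 2.79e-09, and the adjusted p = 0.298 with an estimated correlation. Of 81 ribosome biogenesis genes, 2 rose and 2 fell (0 and 0 when adjusted over the list alone), the median was -0.05 and the camera adjusted p was 0.181. That list was called lower without D126 replicate 2 (adjusted p = 0.0303) or D126 replicate 3 (0.0174). Its highest value was 0.85 with an estimated correlation and 0.451 over the other alternatives. In the synthesis of leucine, histidine and tryptophan, 5 of 24 genes rose and 0 fell (6 and 0 when adjusted over the list alone), with LEU2 and BAT2 each up 0.28. The list had a camera adjusted p of 0.0206, and the adjusted p = 0.565 with an estimated correlation. That call was lost without REF replicate 2 (adjusted p = 0.196) and with quantile normalization (0.0572), with a lowest value of 0.000528 over all alternatives. Of 32 methionine and sulfur genes, 4 rose and 0 fell (2 and 0 when adjusted over the list alone), MET2 by 0.20. For methionine genes camera's adjusted p was 0.0442, and the adjusted p = 0.574 with an estimated correlation. The methionine call was lost with quantile normalization (0.0857) and without REF replicate 1, D12 replicate 2, D126 replicate 2 or D126 replicate 3 (highest adjusted p = 0.122, lowest over all alternatives 0.00487). With the replicate block it was 0.0549 over all arrays and 0.04 with the REF and D126 arrays alone.

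Of 45 cell cycle genes, 19 rose and 0 fell (21 and 0 when adjusted over the list alone), with a median of 0.10. SCW11, a daughter-cell glucanase, rose from 10.44 ± 0.00 to 11.09 ± 0.01 (adjusted p = 1.39e-05), EGT2 by 0.56 and the replication licensing gene CDC6 by 0.46. Cell cycle genes had a camera adjusted p of 4.46e-09, and the adjusted p = 0.298 with an estimated correlation. Of 39 cell wall genes, which also include SCW11, 11 rose and 4 fell (11 and 4 when adjusted over the list alone). UTR2 rose by 0.54 and the mannoprotein gene CWP1 fell by 0.41. The cell wall list had a camera adjusted p of 0.0206, and the adjusted p = 0.477 with an estimated correlation. Fry called both lists (0.00155 and 0.00868). UTR2 was not called without REF replicate 2 (adjusted p = 0.0512, with 0.00016 the lowest over all alternatives).

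Of 7 a-specific genes, which mark MATa cells, 6 rose and 0 fell (7 and 0 when adjusted over the list alone), with a median of 0.39. The a-factor genes MFA1 and MFA2 rose by 0.49 and 0.62, to 13.13 ± 0.07 and 12.50 ± 0.07. These markers had a camera adjusted p of 2.95e-06, and the adjusted p = 0.298 with an estimated correlation. Of 4 alpha-specific genes, 1 rose and 0 fell (1 and 2 when adjusted over the list alone): MF(ALPHA)1 went from 6.11 ± 0.05 to 6.63 ± 0.09, close to the background limit of 5.64. The alpha-specific median was -0.02 and the mean 0.08 (camera adjusted p = 0.832). Of 15 haploid-specific and mating genes, 5 rose and 2 fell (5 and 2 when adjusted over the list alone), with the HO endonuclease gene up 0.49, NEJ1 of end joining falling by 0.47 and the meiosis repressor RME1 by 0.37. The mating list had a camera adjusted p of 0.0312, and the adjusted p = 0.381 with an estimated correlation. Of 28 markers of meiosis and sporulation, 7 fell and 1 rose (7 and 1 when adjusted over the list alone), with SPS100 falling from 13.45 ± 0.13 to 12.55 ± 0.29 and SPS4 rising by 0.57. Sporulation markers had a camera adjusted p of 0.0246, and the adjusted p = 0.575 with an estimated correlation. Their adjusted p was 0.0711 with quantile normalization and at least 0.00388 in the other alternatives.

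Camera thus called 18 of 35 lists for D126 against REF, 11 higher and 7 lower. Fry called 17 lists, 13 of them also called by camera. It did not call the unfolded protein response, leucine, histidine and tryptophan, methionine, mitochondrial ribosome and sporulation lists. Camera with an estimated correlation called 0 (smallest adjusted p = 0.298). Of the 10 splits of the REF and D126 arrays into 3 and 3, only the real one called as many as 18 lists. The highest other count was 16, so the number of list calls sets D126 little apart from REF. Among lists camera did not call, glycolysis and fermentation came closest (3 of 37 genes rose and 13 fell, or 3 and 14 when adjusted over the list alone; camera adjusted p = 0.0511). For the others, camera's adjusted p was 0.0813 for copper, zinc and phosphate, 0.0906 for other amino acids, 0.169 for hexose transport, 0.181 for nitrogen, 0.391 for the proteasome, 0.526 for iron, 0.66 for uracil synthesis and 0.684 for multidrug transport, whose median was -0.02 and mean 0.01. Glycolysis was called without REF replicate 2 (0.0429), D12 replicate 1 (0.0445), D12 replicate 2 (0.0474) or D126 replicate 1 (0.0346), and copper, zinc and phosphate without REF replicate 3 (0.0171) or D126 replicate 2 (0.0245). Other amino acids were called without REF replicate 3 (0.0121) or D126 replicate 1 (0.0346), and nitrogen without REF replicate 1 (0.0466). With an estimated correlation these lists had 0.477, 0.562, 0.613 and 0.519, in that order. Over the other alternatives their highest values were 0.0899, 0.298, 0.602 and 0.234. In uracil synthesis 2 of 10 genes rose and 1 fell (3 and 2 when adjusted over the list alone), its median was 0.03 and its mean -0.03, and fry put it on the lower side (adjusted p = 0.00155).

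**Figure D3:**
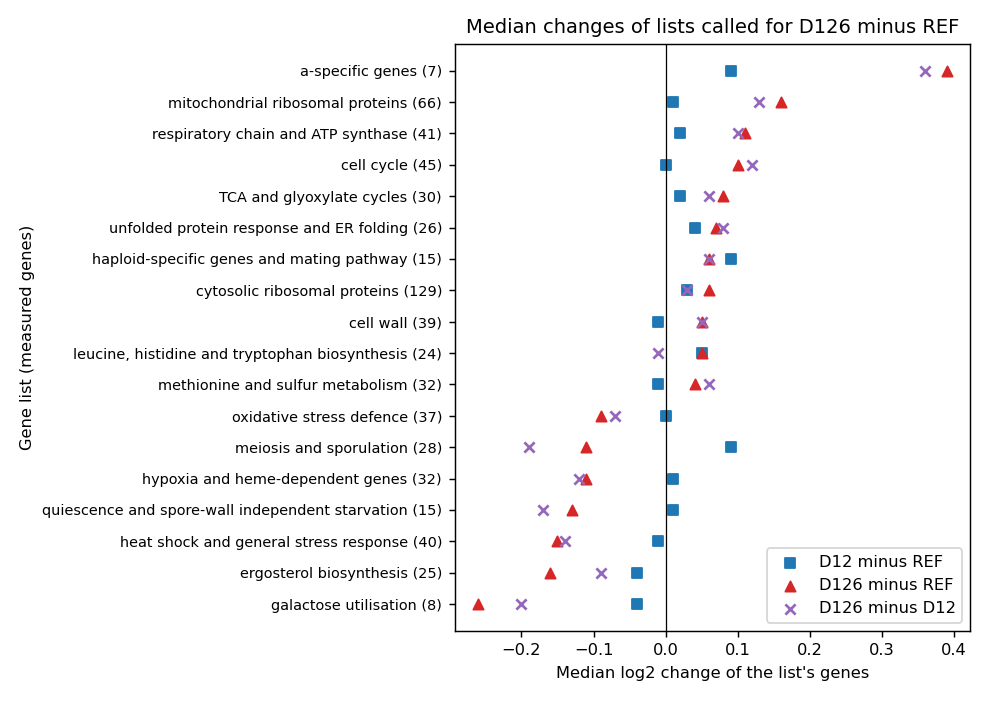
Median log2 change (horizontal axis) of the measured genes of the 18 lists that camera called for D126 minus REF, with the number of genes in parentheses and 1 symbol per comparison (squares D12 minus REF, triangles D126 minus REF, crosses D126 minus D12). For D126 minus REF the medians run from -0.26 (galactose utilisation) to 0.39 (a-specific genes), and the D12 minus REF medians lie between -0.04 and 0.09.

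The third comparison set D126 against D12. Per the labels, D126 expresses the D6-desaturase in addition to the D12-desaturase. Whether the construction of these strains differs in other ways is not described in the sources used here. URA3 was lower in D126 than in D12 (log2 change -1.18, SE 0.03, adjusted p = 9.06e-08), by more if such bright values are compressed. YDL218W had a log2 change of -1.55 (SE 0.10). The mannoprotein gene HPF1 fell from 13.79 ± 0.03 in D12 to 12.51 ± 0.10 in D126, PAU24, PAU2 and PAU5 fell by 1.52, 1.06 and 1.04, and TIR4 fell by 1.10. YNL034W, PRY3 and DSE4 rose at least 2-fold, by 1.08, 1.02 and 1.02, followed by CIT2 (0.84), BAR1 (0.83), SCW11 (0.82), the regulator SFG1 (0.76) and the dicarboxylic amino acid permease gene DIP5 (0.75). HXT15 was below the background limit in both strains.

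Limma called 1200 genes (22.0%) between D126 and D12, 399 higher and 801 lower in D126, a higher share of 33.2%. The split depended on scaling: it was 536 higher and 703 lower (43.3%) with arrays centred on their medians and 593 and 630 (48.5%) with quantile normalization. The 3 values of each strain did not overlap for 2095 genes (38.4%), against 10% by chance. Without D126 replicate 3 the count was 683. It was 780 with only the 6 arrays compared, 2057 with array weights, 655 with all non-control probe sets and 229 by the plain test per gene.

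Heat shock and general stress genes were lower in D126 than in D12, with 20 of 40 falling and 3 rising (23 and 4 when adjusted over the list alone). RTN2 fell by 0.71, HSP30 by 0.75 and HSP31 by 0.61. The camera adjusted p was 2.39e-05, and the adjusted p = 0.595 with an estimated correlation. In oxidative stress defence 15 of 37 genes fell and 2 rose (15 and 3 when adjusted over the list alone), including CTT1 by 0.73, OYE3 by 0.58 and the glutathione peroxidase gene GPX1 by 0.42. The list had a camera adjusted p of 0.0146, and the adjusted p = 0.625 with an estimated correlation. Of the hypoxia and heme-dependent genes, 12 of 32 fell and 0 rose (15 and 1 when adjusted over the list alone), and 8 of 15 quiescence genes fell (8 and 0 when adjusted over the list alone), with camera adjusted p of 0.00114 and 0.00116. The adjusted p = 0.537 and 0.316 with an estimated correlation for these lists. Sporulation markers fell in 9 of 28 cases and rose in 1 (11 and 1 when adjusted over the list alone), with SPO20 falling by 0.59 and SPS100 by 0.63 (camera adjusted p = 0.00163). Their adjusted p = 0.631 with an estimated correlation. Ergosterol genes fell in 9 of 25 cases with 0 rising (9 and 0 when adjusted over the list alone), among them ERG24 by 0.33, IDI1 by 0.29 and ERG7 by 0.23 (camera adjusted p = 0.0017). The adjusted p = 0.631 with an estimated correlation for ergosterol.

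On the higher side, 19 of 45 cell cycle genes rose and 0 fell (21 and 0 when adjusted over the list alone), with EGT2 up 0.68 and the cyclin gene PCL9 up 0.47, and 5 of 7 a-specific genes rose (5 and 0 when adjusted over the list alone), MFA2 by 0.70. Camera's adjusted p was 7.93e-10 and 2.91e-05, and both lists had an adjusted p = 0.316 with an estimated correlation. Of 39 cell wall genes, 12 rose and 4 fell (12 and 4 when adjusted over the list alone), with CHS2 up 0.44 and UTR2 up 0.61 (camera adjusted p = 0.00137). For cell wall genes the adjusted p = 0.595 with an estimated correlation. In the mitochondrial ribosome 18 of 66 genes rose and 1 fell (22 and 1 when adjusted over the list alone), MRP10 by 0.29. In the respiratory chain 6 of 41 rose and 1 fell (6 and 1 when adjusted over the list alone), with ATP14 up 0.20 and the cytochrome c gene CYC1 up 0.23. Camera gave adjusted p of 4.16e-12 and 3.84e-07, and both lists had an adjusted p = 0.625 with an estimated correlation. In the TCA and glyoxylate cycles 7 of 30 rose and 1 fell (7 and 1 when adjusted over the list alone), with IDH1 up 0.39. In cytosolic ribosomal proteins 6 of 129 rose (0 when adjusted over the list alone), RPS22A by 0.18. That share is below the one of all genes called higher (399 of 5449). Camera's adjusted p was 0.00116 and 0.000121, and the adjusted p = 0.631 and 0.595 with an estimated correlation for these lists. In methionine and sulfur metabolism 6 of 32 genes rose and 2 fell (6 and 2 when adjusted over the list alone), with MHT1 up 0.32, and in the unfolded protein response 5 of 26 rose and 1 fell (6 and 2 when adjusted over the list alone), with camera adjusted p of 0.0116 and 0.0235. The adjusted p = 0.631 and 0.669 with an estimated correlation. Quantile normalization ended both of these calls (0.0532 and 0.0521). The methionine call was also lost without D12 replicate 3 (adjusted p = 0.108) and the unfolded protein call without D12 replicate 2, D126 replicate 2 or D126 replicate 3 (highest adjusted p = 0.0999). Over all alternatives but the estimated correlation, the adjusted p was 0.000823 to 0.108 for methionine and 0.0028 to 0.0999 for the unfolded protein response.

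Among the other lipid lists, none of which camera called, CYB5 fell by 0.30 and FAA3 rose by 0.27 in D126 against D12, where 2 of 21 fatty acid genes rose and 6 fell (3 and 7 when adjusted over the list alone). In this list and in mitochondrial fatty acid synthesis camera pointed up while the mean was -0.01 and -0.02. OLE1 differed by -0.11 (adjusted p = 0.0589, from 0.0211 to 0.189 over the alternatives), CBR1 by 0.08 and INO1 by -0.15. MGA2 fell by 0.13 (adjusted p = 0.0365) and SPT23 by 0.22 (0.0327). MGA2 was not called without REF replicates 1 or 2, D12 replicates 2 or 3 or any D126 replicate (up to 0.104; 0.0134 to 0.135 over all alternatives). SPT23 was not called without REF replicate 2 or any D126 replicate (up to 0.0856; 0.018 to 0.178 over all alternatives). CBR1 had an adjusted p of 0.215, of 0.0304 without D12 replicate 1 and of 0.0191 to 0.443 over all alternatives. For INO1 it was 0.0732, 0.018 without D12 replicate 1 and 0.0092 to 0.254 over all alternatives. PIS1, the phosphatidylinositol synthase gene, rose by 0.31, GEP4 by 0.29 and SLC1 by 0.32, while INO2 fell by 0.27. AYR1 fell by 0.32, SKN1 by 0.26, YPC1 by 0.28, ECI1 by 0.44 and ETR1 of mitochondrial fatty acid synthesis by 0.31. The genes that rose and fell were 2 and 2 in mitochondrial fatty acid synthesis (3 and 2 when adjusted over the list alone), 3 and 1 among phospholipid genes (3 and 1), 2 and 3 in triacylglycerol and steryl ester metabolism (2 and 4), 5 and 5 among sphingolipid genes (6 and 6) and 2 and 8 in peroxisomal beta-oxidation (2 and 8). Camera called the phospholipid list without D126 replicate 1 (adjusted p = 0.0322). Its adjusted p was 0.625 with an estimated correlation and at most 0.41 in the other alternatives. In total camera called 15 lists, 9 higher and 6 lower, fry called 14, with 11 in common, and the 3 that fry alone called were glycolysis, galactose and uracil. Camera with an estimated correlation called 0 (smallest adjusted p = 0.316). Of the 10 splits of the D126 and D12 arrays into 3 and 3, 3, the real one included, called at least 15 lists. The highest other count was 16, so the number of list calls does not set D126 apart from D12.

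D126 was called different from both other strains for 879 genes, all in the same direction in both comparisons. Of these 294 were higher, where independent lists would share 34, and 585 were lower, where independent lists would share 104. The log2 changes of these comparisons correlated across genes with r = 0.91, against 0.49 in simulations with no effect, and their covariance was 0.028 against 0.002, a difference of 0.026. Genes are not independent replicates, and part of the excess may come from the D126 arrays that both comparisons share. Since limma called 0 genes for D12 against REF, 0 could be called in both D12 and D126 against REF. AAD3 differed from REF by similar amounts in both strains, by -0.99 in D12, where it was not called, and by -0.95 in D126, where it was, on a shared probe set and chosen here after its values were seen. Its other probe sets differed less, by -0.33 and -0.08 in D12 and by -0.28 and -0.14 in D126. The D12 and D126 changes correlated across genes with r = 0.20, where unchanged strains set against the same REF arrays gave 0.50. Their covariance was 0.0026 against a simulated 0.0020, a difference of 0.0006, and 57.1% of genes had the same sign against 66.7% in simulations. The simulations gave neither strain an effect, whereas 1173 genes were called for D126 minus REF. Effects in D126 alone lower the correlation and the share of equal signs. The lower values therefore do not show that the changes of the 2 strains oppose each other. The F-test called 1096 genes with any strain difference. It called 723 without REF replicate 2, 705, 678 and 538 without D126 replicates 1, 2 and 3 respectively, and 2568 with array weights.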

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

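The tests of RNA degradation, faster growth, a faulty probe set and the activator Ppr1 were chosen only after the results were seen.

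Probe sets outside the tested genes also differed between strains. Of 3470 probe sets with no gene in the table, limma called 8 for D126 minus REF, 2 higher and 6 lower, and 13 for D126 minus D12, 6 higher and 7 lower. For D12 minus REF it called 0, with 179 at an unadjusted p under 0.05. The largest log2 changes among those of D126 minus REF were 1.03 and 0.94 on the higher side and -1.39 and -0.87 on the lower. Among 213 array control probe sets, 3 were called for D126 minus REF, and all of these were URA3 controls. For D126 minus D12 the count was 5, these and a pair of reporter probe sets that changed by 1.46 (8.26 ± 0.14 in D126 and 6.80 ± 0.53 in D12, adjusted p = 0.0244) and by -0.45 (13.00 ± 0.06 and 13.45 ± 0.12, adjusted p = 0.0465). Of 1747 probe sets for genes outside the yeast table limma called 0 in each comparison, with 72, 93 and 94 at an unadjusted p under 0.05 for D12 minus REF, D126 minus REF and D126 minus D12.

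The first pattern is that the D126 arrays stood apart from the REF arrays: of the 10 splits of the 6 arrays into 3 and 3, only the real split, 1 of 10, called 1173 genes, against 0 as the highest other, and 10 splits are too few for a share under 0.05. Whole-chromosome gain or loss is argued against by the chromosome farthest from 0, with a median change of 0.03 among 16 chromosomes, and faster growth by the ribosome biogenesis median of -0.05 (95% interval -0.06 to -0.03 when resampling genes), where a rise was needed. The mean of that list was -0.04 with an SE over arrays of 0.05, so a small rise of the list is not excluded. Cytosolic ribosomal protein and cell cycle genes went the other way, with medians of 0.06 and 0.10. Per the labels, all cultures were at steady state at the same dilution rate of 0.1 per h, which sets the growth rate in a chemostat. The fixed dilution rate therefore argues against a different growth rate, whichever way these lists moved. RNA degradation is not excluded as a part of the difference, since the 3′ minus 5′ difference of 7 control transcripts changed by 0.06 (SE 0.03). The limit set for that test, 0.1, lies within 2 SE of this change. The arrays do not order by this measure, which argues against it as the whole cause. D126 replicate 1 and REF replicate 2 both had 0.79 but lay at 10.18 and -4.42 on component 1. D12 replicate 1 had 0.83 and lay at -2.40, on the side of the REF arrays. The introduced desaturase genes are the biological difference the design names and remain untested, as does a difference of hybridisation date, for which no label was available here.

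The second pattern is the lower URA3 signal in D126, and a faulty probe set is argued against by 3 control probe sets for URA3, which changed by -1.17, -1.41 and -1.63. Loss of a chromosome segment at the native URA3 locus is argued against by its measured neighbours (R64 gene order). The lowest change among them, of MMS21, was -0.18 (SE 0.06), close to the limit of -0.2 set for the test. The neighbours cannot tell whether the signal comes from a copy of URA3 placed elsewhere. By its mean in REF, the URA3 probe set ranked 6 from the top of the array. Lower activity of the activator Ppr1 is argued against as the whole cause by its targets URA1 and URA4, of which the lower change was 0.05 for URA4, while URA1, chosen after its values were seen, rose by 0.62 (adjusted p = 0.000283). URA10, a further target, and PPR1 itself went the way it predicts, by -0.17 (adjusted p = 0.0676) and -0.14 (adjusted p = 0.101), so a part in the change stays open. A different copy number or promoter context of a URA3 marker in the strain construction may also lower the signal and stays open, because the construction is not described in the sources used here.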

How the results depend on the processing

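All alternatives in this part were planned except the replicate block with 6 arrays, and the cause of a change was not tested. With all non-control probe sets, which means more tests, limma called 630 genes for D126 minus REF, 655 for D126 minus D12 and 583 by the F-test. With array weights, which ran from 0.19 for D12 replicate 3 to 5.22 for D126 replicate 3, it called 2615, 2057 and 2568, and 1 for D12 minus REF. A 2-fold minimum left 7 and 12 genes. For D126 minus D12, only the 6 arrays compared gave 780 and the plain test per gene 229. Quantile normalization gave 1 gene for D12 minus REF. Camera with an estimated correlation called 0 lists for D12 minus REF, 0 for D126 minus REF and 0 for D126 minus D12. Leaving out 1 array gave 0 to 1 genes and 6 to 11 lists for D12 minus REF. It gave 645 to 1539 genes and 18 to 20 lists for D126 minus REF, 683 to 1332 genes and 15 to 16 lists for D126 minus D12, and 538 to 1292 genes by the F-test.

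The replicate block gave 0, 922 and 964 genes for D12 minus REF, D126 minus REF and D126 minus D12, and 817 by the F-test, and 10, 17 and 15 lists. For D126 minus REF, for which the block was weighed, it ended 1 list call, methionine, and changed no other list. With the REF and D126 arrays alone it called 1603 genes, 1137 of the 1173 among them, and the same 18 lists. In no comparison do the labels say that same-numbered arrays share more than a number. Among called genes picked by the naming rule, not all of which the text names, calls were kept in 957 of 995 gene-by-alternative results for D126 minus REF and 693 of 747 with 1 array left out. For D126 minus D12 they were kept in 782 of 857 and 649 of 702, and none reversed. The differences of D12 minus REF that changed sign were not called. CBR1 had -0.0045 with arrays centred on their medians, -0.00025 with quantile normalization and -0.0071 with array weights, and -0.037 to 0.037 without 1 array. OLE1 had -0.016 when centred and -0.017 with quantile normalization, and -0.0043 to 0.011 without 1 array. With array weights GAS4 had -0.019 and SPT23 -0.046. Without 1 array they ran from -0.044 to 0.36 and from -0.052 to 0.067. The correlation of the D12 and D126 effects was 0.20 with all genes and with genes above background. Signal limits few genes, as 5332 of 5449 lay above the background limit.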

Other observations

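The test of mixed cells was chosen only after the results were seen, while the splits of the arrays were planned.

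The seripauperin family, whose members were picked after their values were seen, has members that fell in D126, and no test covers the family as a whole. Of 13 PAU genes, 10 of them on shared probe sets that mix family members, 8 were called lower and 0 higher in D126 than in REF, with a median of -0.60 and a range of -1.48 to 0.08. The other 5 were not called: PAU8 (0.00), PAU14 (0.08), PAU4 (-0.38), PAU17 (-0.19) and PAU23 (-0.10), though a dimmer probe set of PAU17 (-0.41) and of PAU23 (-0.15) was called lower. Against D12 the counts were the same and the median was -0.63. Between D12 and REF limma called 0 of them, with a median of -0.05.

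In uracil synthesis, no gene other than URA3 was called lower in D126 than in REF when adjusted over all genes, while 2, URA3 among them, were called lower when adjusted over the list alone. URA1 rose from 12.22 ± 0.10 to 12.83 ± 0.05, and URA2, also chosen after its values were seen, rose by 0.20 (adjusted p = 0.0017). URA4 differed by 0.05, URA5 by 0.00 and URA10 by -0.17 (adjusted p = 0.0676). Against D12, URA10 fell by 0.25 (adjusted p = 0.0165). These genes, too, were named after their values were seen.

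The third pattern is that a-specific genes were higher in D126. A smaller share of cells lacking a-specific transcripts would raise all a-specific genes by the same factor, and the largest and smallest change, of BAR1 and AGA2, differed by 0.75 (SE 0.08), which argues against it as the whole cause. An effect of the introduced desaturases on these genes was not tested.

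Other splits of the arrays gave the following counts. For D12 minus REF, 10 of 10 splits called as many genes as the real one (0 genes; highest other 11), and 6 of 10 called as many lists (11 lists; highest other 14). For D126 minus REF, 1 of 10 called as many lists (18; highest other 16). The real split parts all 3 same-numbered pairs, as do 3 others, which called 0 genes and at most 16 lists; the 6 that part 1 pair also called 0 genes and at most 16 lists. For D126 minus D12, 1 of 10 called as many genes (1200; highest other 0) and 3 of 10 as many lists (15; highest other 16). The 10 splits of 6 arrays are too few for a share under 0.05. For the F-test, 2 of 100 drawn splits of the 9 arrays, the real one included, called as many genes as the real split (1096), the highest other being 1130. That share is under 0.05, but it treats the arrays as independent, which the labels do not show. Chance differences between cultures or batches are therefore not excluded by it. The 5 other drawn splits that kept the D126 arrays together called 947 to 1130 genes, while the 94 that parted them called at most 2, so the F-test count follows the place of the D126 arrays.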
